A study of Arabidopsis thaliana with 8 samples.

How the data were processed

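RNA from whole Arabidopsis thaliana plants was measured on 8 Affymetrix ATH1 arrays. Plants of 4 lines were grown in sterile sand with nutrient solution at 1 or 12.5 mM CaCl2: a laboratory calcicole, a laboratory calcifuge, a wild ecotype from high soil pH and a wild ecotype from low soil pH. A calcicole grows on lime-rich soil and a calcifuge avoids it. Each line and dose has 1 array, so no line was replicated within a dose.

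The deposited values are a signal intensity per probe set, made by the authors with MAS5, whose version and settings are not given. The values are linear and were already scaled between arrays: the mean without the lowest and highest 2% of values was 100.0 on each of the 8 arrays. Detection calls were not used here. For arrays the precision is limited by their number.

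Of 22810 probe sets, 64 control probe sets were left out. A pseudocount of 2.507, the 10th percentile of the deposited gene values, was added before taking log2, and no further scaling was applied. The 40% of probe sets with the lowest mean log2 value were left out, which left 13647 probe sets tested. The platform table pairs 13513 probe sets with 1 gene and 503 with several genes, and leaves 8730 unnamed here. Gene identifiers of 13436 single-gene probe sets matched the reference annotation, TAIR10.1, which was used for names only. Among the tested probe sets 7289 name 1 gene, for 7227 genes.

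Fits used limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over the 13647 probe sets, and an adjusted p under 0.05 as the threshold. The CaCl2 response and the line differences came from an additive model of line and dose with 3 residual degrees of freedom. In it the spread is the departure of the lines from 1 shared dose effect, and the lines serve as replicates of the dose. Differences in the CaCl2 response between calcicole-class and calcifuge-class lines (high soil pH set beside calcicole), and between lab and wild lines, were interaction terms with 2 residual degrees of freedom. The difference between the lab and the wild line differences was tested in the additive model. Errors are standard errors (SE) from these fits. Signs shared by the line comparisons were compared with a two-sided Fisher's exact test.

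Gene lists with 383 members in all were fixed before the data were examined, as were the comparisons, the settings, the alternative settings and the rule for naming genes. Only 46 members are named on the array and 33 were tested, and the anthocyanin and flavonoid list, with 5 tested of 17, was the only list to reach the minimum of 5. List shifts were tested with limma's camera (preset inter-gene correlation 0.01, two-sided), adjusted over 4 comparisons, with camera at an estimated correlation and with fry as alternatives. Further gene sets were chosen after the leading genes had been seen. They were 3 lists written from general knowledge (hypoxia core response, iron-deficiency loci, salicylic acid-responsive loci; 15 tests over 5 comparisons) and 16 families (the plastid-encoded genes and 15 families by gene symbol; 80 tests). For the 3 lists, members whose values had already been seen were left out of the test.

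The named genes are the 12 with the largest difference each way past the threshold among probe sets naming 1 gene. Where fewer passed, the rest are genes that moved the same way in all 4 lines (or at both doses), ranked by the smallest of those changes. For each interaction, where none passed, the 5 with the smallest p each way are named, which are not always the largest. Members of the fixed lists may be named beside these.

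The calculation was tested on simulated data with 200 changed of 13647 probe sets. At 4-fold, 97% were recovered for the CaCl2 response, 88% for the lab comparison, 93.5% for the wild comparison and 0% for the soil class difference in response. At 2-fold, 0% were recovered in each of these 4 comparisons. False calls made up 3.96%, 7.85% and 6.03% of calls at 4-fold in the first 3. In the simulated line comparisons the lines did not differ otherwise. The recovery does not carry over to the lab comparison of the real arrays, where 618 probe sets passed and the adjustment was less strict. Nor does it carry over to the real CaCl2 and wild comparisons, where 2 and 45 passed and the adjustment was stricter. The simulated CaCl2 change was also the same in each line. Real CaCl2 changes above 4-fold, such as AT1G47400 at log2 2.34, did not pass.

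Alternatives covered the scaling, the pseudocount, the filter, the variance model, the threshold, probe sets shared between genes, the line block, and leaving out each line or array. Figures were drawn with matplotlib 3.10.9. Probe sets assigned to several genes or to none stayed in the counts, but no gene was named from them. The probe set of PDF1.2b is paired with 1 gene but is of the type that can also bind other transcripts.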

Results

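Expression was measured in whole plants of 4 Arabidopsis lines grown at 1 and 12.5 mM CaCl2, with 1 array per line and dose, 8 arrays in all. Values are signal intensities, and differences are on the log2 scale with the standard error of the limma fit. The median signal per array was between 42.4 and 47.8. Arrays of the same line at the other dose correlated at 0.917 to 0.948 across probe sets, arrays of different lines of the same origin at 0.83 to 0.944, and arrays of different origin (lab against wild) at 0.819 to 0.908. These ranges overlap: the wild arrays at 12.5 mM correlated at 0.944 with each other, and the wild low soil pH arrays at 0.931 across doses. The first principal component, with 35.3% of the variance, separated the lab arrays from the wild arrays.

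The first comparison asked how the transcriptome responds to a 12.5 mM against a 1 mM CaCl2 supply in all 4 lines. Anthocyanin genes were among those that differed in all 4 lines. UF3GT, a glycosyltransferase of anthocyanins, was 3.85-fold higher at 12.5 mM (log2 1.94 ± 0.23, adjusted p 0.0724, 4 lines), with signals of 113 and 441 in the lab calcicole and 120 and 847 in the lab calcifuge. DFR, the dihydroflavonol reductase, differed by 1.60 ± 0.21, the anthocyanin malonyltransferase AT5MAT by 1.72 ± 0.25, the anthocyanidin glucosyltransferase AT4G14090 by 1.48 ± 0.23 and UGT78D2 by 1.24 ± 0.34. Each of these 5 was higher in all 4 lines, and none passed the threshold over all probe sets. All 5 passed when adjusted over the list alone.

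As a list, anthocyanin and flavonoid synthesis had a mean change of 1.60, with means per line of 1.68 in the lab calcicole, 2.48 in the lab calcifuge, 1.13 in the wild high soil pH line and 1.1 in the wild low soil pH line. Its camera adjusted p was 3.81e-09 at the preset correlation, and the estimated-correlation adjusted p was 0.260. With fry the adjusted p was 0.0541. An exact two-sided sign-flip test over the 4 lines gave p 0.125, the smallest it allows.

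Other genes, named because they were higher in all 4 lines, did not pass the threshold. AT1G47400, a short peptide gene of the iron-deficiency response, had the largest difference of the named higher genes, 2.34 ± 0.45 (adjusted p 0.108). Its signal was 35.7 and 670 in the lab calcicole, 39.0 and 84.1 in the lab calcifuge, 104 and 323 in the wild high soil pH line, and 159 and 947 in the wild low soil pH line. CHIL, a chalcone isomerase-like gene, differed by 1.45 ± 0.29, AT4G32920 by 1.97 ± 0.34, AT5G62210 by 1.62 ± 0.25, AT2G21820 by 1.67 ± 0.34, the methionine gamma-lyase MGL by 1.18 ± 0.17, AT5G12110 by 1.11 ± 0.15 and AT1G79520 by 1.07 ± 0.18. AT4G32920 was at 2.44 in the lab calcifuge at 1 mM, under the pseudocount of 2.507. For AT5G62210 the change was 2.59 in the lab calcicole and 1.14 to 1.37 in the other lines.

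Further genes were named because they were lower at 12.5 mM in all 4 lines. AT5G03350, a lectin-like gene, differed by -1.82 ± 0.26 (adjusted p 0.0736), the defensin gene PDF1.2b (4.62 in the wild high soil pH line at 12.5 mM) by -2.07 ± 0.37, the carboxylesterase-like AT1G68620 by -2.01 ± 0.31 and the calcium-binding AT3G47480 by -1.17 ± 0.15. AT5G08240 differed by -2.36 ± 0.30, with wild signals at 12.5 mM of 4.12 and 5.29, close to the pseudocount of 2.507, on which the size of the difference depends. AT3G48640 differed by -1.87 ± 0.31, AT1G25400 by -1.91 ± 0.38, AT3G06070 by -1.51 ± 0.18, AT2G25735 by -1.46 ± 0.15, AT5G24210 by -1.43 ± 0.16, AT3G15770 by -1.25 ± 0.16 and AT2G44500 by -1.15 ± 0.15. None of these passed the threshold.

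Members of the other fixed lists did not pass the threshold. The glutaredoxin gene GRX480 differed by -1.33 ± 0.22 (adjusted p 0.0831), PDF1.2 by -1.93 ± 0.73, EXPA8 by -1.19 ± 0.28 and the root beta-glucosidase gene PYK10 by 1.17 ± 0.29. The calcium sensors CML38 and CML42 differed by -0.81 ± 0.38 and -0.71 ± 0.22. COR15A differed by 0.67 ± 0.21, LTI30 by 0.90 ± 0.41 and the iron regulator PYE by 0.44 ± 0.15. The 4 photosynthesis genes RCA, LHCB4.1, PSAE-1 and PRK differed by -0.33, -0.28, -0.17 and -0.09.

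**Figure D1:**
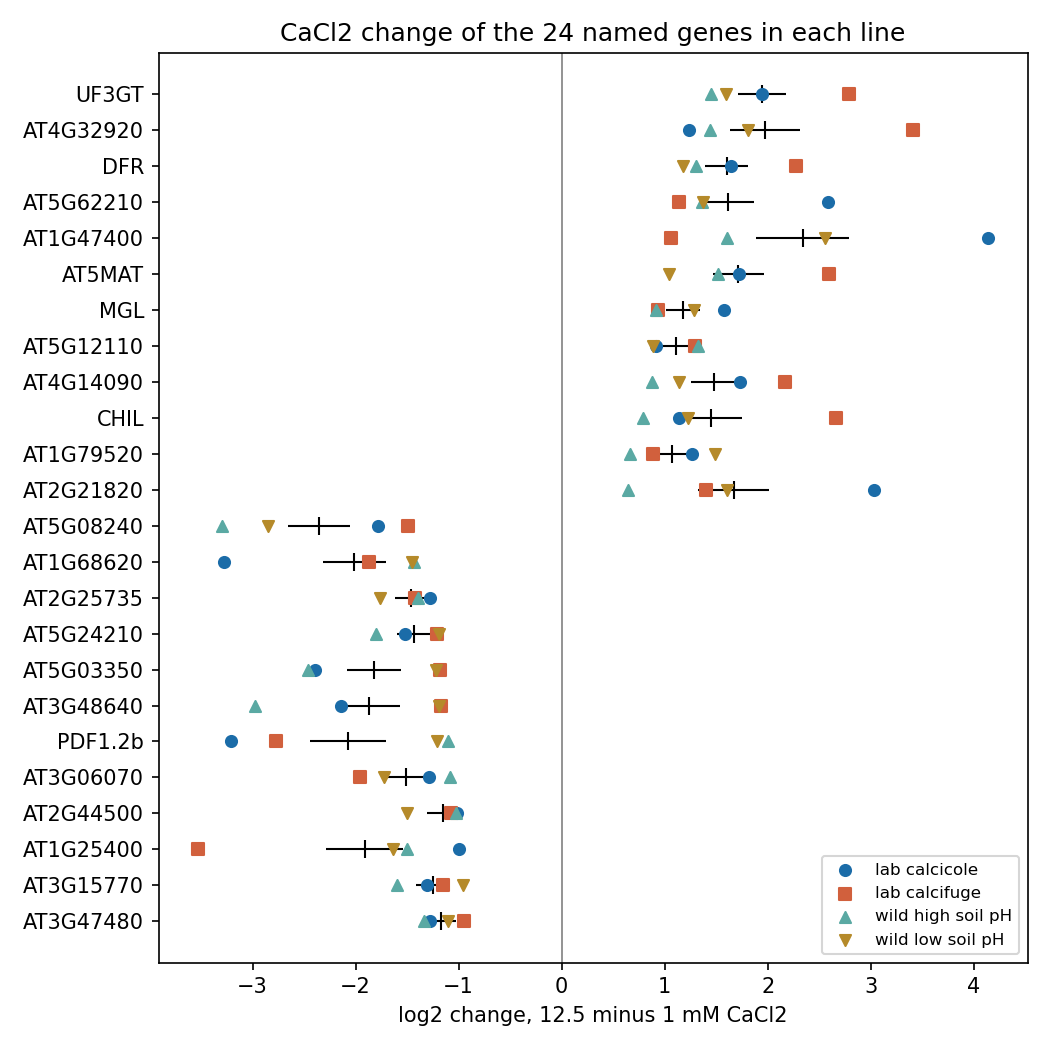
Change with CaCl2 (log2, 12.5 minus 1 mM) of the 24 named genes, 1 point per line, with the fitted change and its SE in black. All 24 were named because they moved the same way in each of the 4 lines, so this agreement is not a result. UF3GT changed by 1.45 to 2.79 and AT5G08240 by -3.30 to -1.49.

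Over all 13647 probe sets 2 passed the threshold, both lower at 12.5 mM, and 1779 had an unadjusted limma p under 0.05, where 682 are expected by chance. One is assigned to 2 genes (-1.91 ± 0.15, adjusted p 0.0296), and the other is unnamed here (-2.06 ± 0.17, adjusted p 0.0301). The count past the threshold was 78 without the lab calcifuge, 1 without the lab calcicole, 0 without the wild high soil pH line and 4 without the wild low soil pH line. At an adjusted p under 0.1, 103 probe sets passed, 28 higher and 75 lower. At least a 2-fold change in the same direction in all 4 lines was seen for 26 probe sets, 10 higher and 16 lower, against 0 to 4 for each of the 7 other patterns of sign. Across probe sets, which are not independent replicates, the CaCl2 changes of pairs of lines correlated at 0.08 to 0.33.

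The next comparison asked how the lab calcicole differs from the lab calcifuge. AT3G48640 was higher in the calcicole (6.30 ± 0.43, adjusted p 0.00147, 2 arrays per line), with signals of 1299 and 293 in the calcicole and 9.28 and 2.73 in the calcifuge. The second of these is close to the pseudocount of 2.507, as is the signal of AT1G71020 in the calcicole at 12.5 mM (2.77), and AT2G15020 was under it in the calcifuge at 1 mM (0.69), so the size of these differences depends on the pseudocount. AT4G29200 was higher by 4.21 ± 0.24, AT2G29170 by 3.90 ± 0.54, AT2G15020 by 3.13 ± 0.56, AT5G16980 by 3.05 ± 0.35 and AT5G15360 by 2.98 ± 0.22. AT4G29200 was low in the calcifuge (7.58 and 6.76), so the size of its difference depends on the pseudocount too. The linker histone gene HIS1-3 was higher by 2.72 ± 0.50 and MPC by 2.70 ± 0.29. AT2G35820, AT5G43450, AT1G64500 and AT5G09570 were higher by 2.79, 2.66, 2.42 and 2.39.

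Lower in the lab calcicole were AT3G07540 (-4.03 ± 0.29), AT5G35480 (-3.85 ± 0.29), AT3G19515 (-3.82 ± 0.27) and the resistance-gene homologue AT3G44630 (-3.65 ± 0.21). The first 3 were near the pseudocount in the calcicole at 1 and 12.5 mM (4.4 and 3.23, 7.56 and 4.85, 10.1 and 5.28), so their sizes depend on it. The thionin gene THI2.2 differed by -3.57 ± 0.39, at 4.45 and 6.99 in the calcicole against 131 and 67.3 in the calcifuge, and was between 543 and 1471 in the wild lines. The endoglucanase gene GH9B13 differed by -3.20 ± 0.49 and SKU5, a gene of directional root growth, by -3.04 ± 0.31. AT4G15390, AT1G71020, AT1G06640, AT5G12050 and AT5G63680 differed by -3.53, -3.28, -3.09, -2.98 and -2.97. Of the fixed list members, PYK10 (-2.14 ± 0.41, adjusted p 0.0350) and DFR (-1.49 ± 0.29, adjusted p 0.0365) were lower past the threshold, and EXPA4 was at -1.01 ± 0.22 (adjusted p 0.0503). The anthocyanin list had a mean of -0.60 (camera adjusted p 0.138).

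In total 618 probe sets differed between the lab lines, 209 higher and 409 lower in the calcicole, and 591 of them by at least 2-fold. With each array centred on its median the share higher was 42.7%, against 33.8% here. The count fell to 123 and 138 without the calcicole array at 1 or 12.5 mM, and to 201 and 305 without the calcifuge array at 1 or 12.5 mM. The comparison concerns these 2 lines and not calcicoles in general. Sequence variants under the probes may add to the total, and how many probe sets they affect was not tested.

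The wild lines were compared in the same way, high minus low soil pH. The subtilase gene AT4G21650 was higher in the high soil pH line (6.30 ± 0.36, adjusted p 0.00119, 2 arrays per line), with signals of 325 and 272 against 2.21 and 0.57 in the low soil pH line, and AT3G47250 was higher by 6.02 ± 0.53, with signals of 1.28 and 12.1 in the low soil pH line and 347 to 536 on the other 6 arrays. Signals under the pseudocount of 2.507 make the size of both differences depend on it. AT4G29200 was higher by 4.1 ± 0.24, AT4G36210 by 3.06 ± 0.22, the resistance-gene homologue AT5G47250 by 2.51 ± 0.25 and AT4G12990 by 1.88 ± 0.20. AT5G46390 and AT5G37130 were higher by 1.61 and 1.46. The genes 2A6, AT3G60300, AT5G04080 and AT2G15020 differed by 2.29, 2.02, 2.24 and 2.4 at both doses in the same direction and did not pass the threshold.

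Lower in the wild high soil pH line were AT5G51620 (-4.45 ± 0.30), the leucine-rich repeat gene AT3G43740 (-4.38 ± 0.34), the flavonol rhamnosyltransferase gene UGT78D1 (-4.20 ± 0.45) and AT4G20480 (-3.82 ± 0.23). AT5G51620 (2.04 and 1.03) and, at 1 dose, GLR2.7 (2.48) were under the pseudocount of 2.507 in this line, and AT3G43740 (2.63) and AT5G25440 (2.77) close to it. UGT78D1 had signals of 3.89 and 4.22 in this line and of 57.4 to 178 on the other 6 arrays. The glutamate receptor-like gene GLR2.7 differed by -3.16 ± 0.29, CYP71B24 by -2.91 ± 0.35 and scpl42 by -2.70 ± 0.20. AT2G19310, AT5G25440, AT3G16700, AT2G30990 and AT3G57220 differed by -2.17, -2.17, -2.07, -1.91 and -1.72. The anthocyanin list had a mean of -0.38 (camera adjusted p 0.138).

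In total 45 probe sets differed between the wild lines, 17 higher and 28 lower at high soil pH, each by at least 2-fold. The count was 9 and 21 without the low soil pH array at 1 or 12.5 mM, 12 and 15 without the high soil pH array at 1 or 12.5 mM, and 27 without either lab calcicole array. Sequence variants under the probes may add to this total too.

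The lab and wild comparisons were set side by side to ask whether the same genes separate the calcicole from the calcifuge and the high from the low soil pH line. AT4G29200 was higher in both (4.21 and 4.1) and scpl42 lower in both (-2.78 ± 0.20 and -2.70 ± 0.20). AT5G51620 was also lower in both, by -1.37 and -4.45. NRPE7, a subunit gene of RNA polymerase V, went opposite ways (1.03 and -1.69), as did AT4G12990 (-1.22 and 1.88). Of 14 probe sets past the threshold in both, 8 had the same sign (2 higher, 6 lower) and 6 the opposite sign, and a two-sided Fisher's exact test of sign against sign gave p 1. Independent lists would share 1.1 probe sets of the same sign and 0.94 of opposite sign. Both comparisons use the same estimate of spread for each probe set, which favours the same probe sets in both lists. A sequence variant carried by 1 lab and 1 wild line may also place a probe set in both lists, with either sign. The larger counts, seen for both signs, thus do not show that the line differences are shared. Of the 45 wild calls 26 had the same sign in the lab comparison, and of the 618 lab calls 357 had the same sign in the wild comparison. Across tested probe sets, which are not independent replicates, both differences correlated at 0.116 (Pearson) and 0.122 (Spearman). The difference between the lab and the wild difference itself passed for 158 probe sets.

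**Figure D2:**
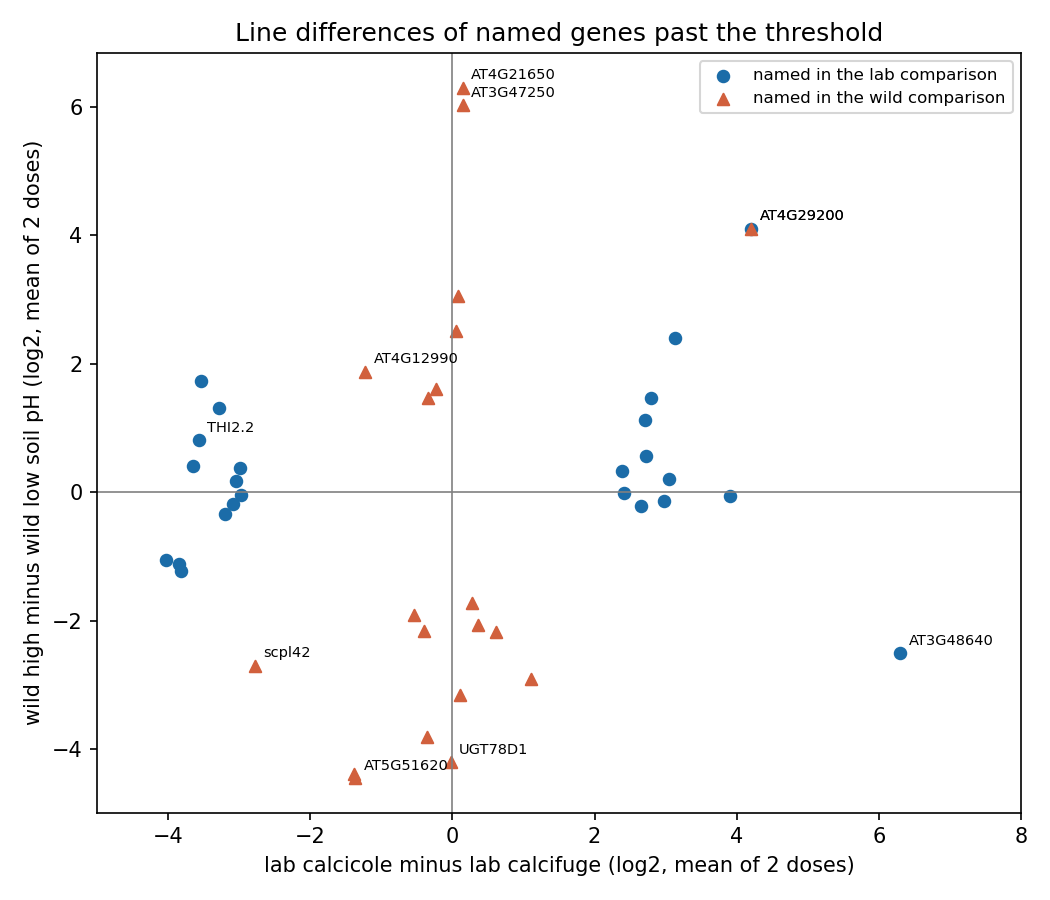
Lab line difference (calcicole minus calcifuge, horizontal) against wild line difference (high minus low soil pH, vertical), log2, mean of both doses, for the named genes past the threshold in either comparison. AT4G29200 lies high and scpl42 low on both axes, while AT4G21650 and AT3G47250 lie at 6.30 and 6.02 on the vertical axis and at 0.14 and 0.15 on the horizontal axis.

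Among the 6 pairs of lines, the lab calcicole differed from the wild high soil pH line at 1277 probe sets and from the wild low soil pH line at 1165. The lab calcifuge differed from these at 788 and 336. In at least 1 pair 2329 probe sets differed, 17.1% of those tested, against 460 with no filter.

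The CaCl2 response was then compared between the calcicole-class lines (lab calcicole, wild high soil pH) and the calcifuge-class lines. AT1G19530 had changes of 3.38 and 3.48 in the lab calcicole and the wild high soil pH line and of -1.45 and -0.61 in the lab calcifuge and the wild low soil pH line, a difference of 4.46 ± 0.37 (adjusted p 0.199). AT4G39675 differed by 5.57 ± 0.86, XTH33 by 3.93 ± 0.36, AT4G10270 by 3.02 ± 0.30 and AT3G10040 by 2.53 ± 0.34. AT4G39675 was at 2.46 and 2.22 in the calcicole-class lines at 1 mM, under the pseudocount of 2.507, and XTH33 at 3.83 in the lab calcifuge at 12.5 mM, close to it, so the size of both differences depends on the pseudocount. The signal of AT1G19530 at 1 mM was 43.8 and 9.88 in the calcicole-class lines and 908 and 145 in the calcifuge-class lines. AT4G33040, AT3G51330, AT1G35710, UGT72B3 and AT1G68600 differed the other way, by -1.86, -1.73, -1.63, -1.62 and -1.46. In limma 0 probe sets passed, and 805 had an unadjusted p under 0.05, where 682 are expected by chance. Without the wild high soil pH line, which leaves the lab calcicole alone in its class, 5 passed. The anthocyanin list had a mean of -0.39 (camera adjusted p 0.2, estimated-correlation adjusted p 0.612). With 1 line left out, and so a class of 1 line, its adjusted p was 0.000374 without the wild low soil pH line, 0.847 without the wild high soil pH line and 0.0748 without the lab calcicole, and without the lab calcifuge its direction reversed (0.164).

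The CaCl2 response was also compared between lab and wild lines, and 4 of the 5 genes named as lower in the lab lines are encoded in the plastid. The difference was -2.87 ± 0.49 for the ATP synthase gene atpI, -2.12 ± 0.36 for atpH, -2.10 ± 0.31 for the photosystem gene psbB and -2.02 ± 0.37 for the plastid RNA polymerase gene rpoB (adjusted p 0.988 each). The signal of psbB at 1 and 12.5 mM was 498 and 150 in the lab calcicole, 353 and 81.3 in the lab calcifuge, 280 and 323 in the wild high soil pH line, and 448 and 514 in the wild low soil pH line. PDF1.2b differed by -1.83 ± 0.32. AT5G09480, AT5G23460, AT4G38080, AT1G72900 and SAL2 differed by 2.21, 1.78, 1.77, 1.74 and 1.73. In limma 0 probe sets passed, and 687 had an unadjusted p under 0.05, where 682 are expected by chance. Without the wild low soil pH line, which leaves 1 wild line, 1 passed.

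**Figure D3:**
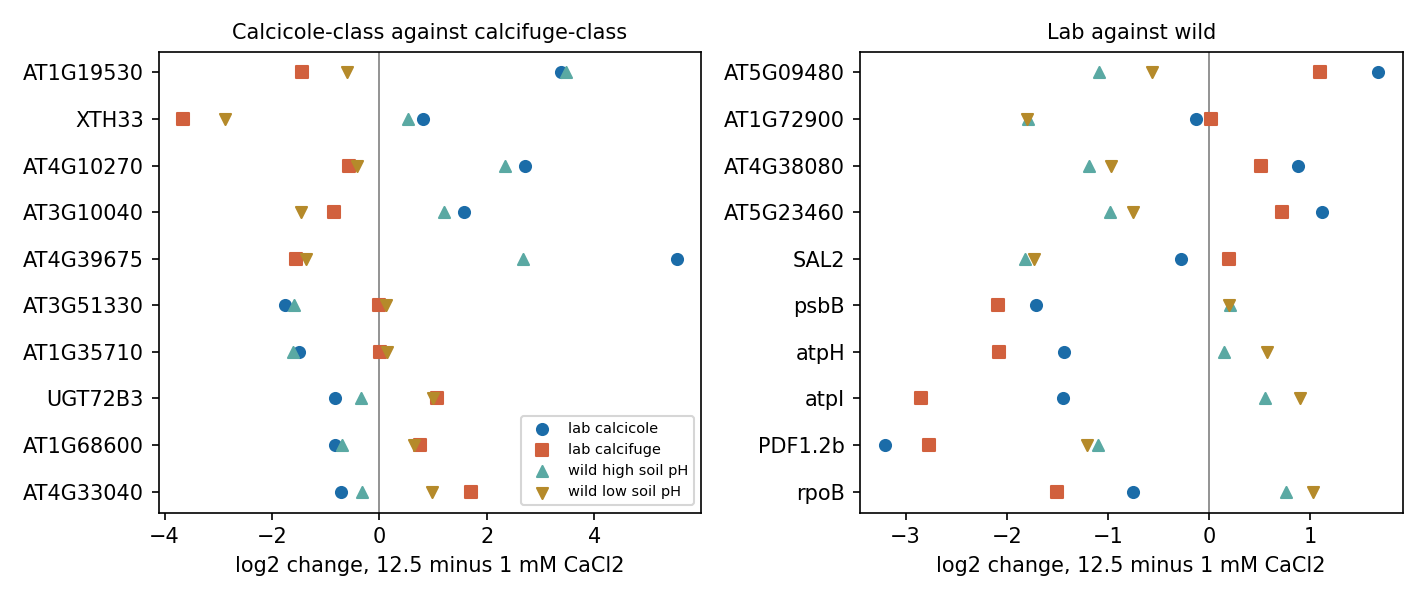
Change with CaCl2 (log2, 12.5 minus 1 mM) in each line of the 10 genes named for the soil class comparison (left) and the 10 named for lab against wild (right). AT1G19530 is at 3.38 and 3.48 in the calcicole-class lines and at -1.45 and -0.61 in the calcifuge-class lines.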

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

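The test of the other probe sets in this part was set before its result was seen; the genes it weighs were seen first.

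AT3G48640 has the largest gap between the lab and the wild line difference among the named genes: calcicole minus calcifuge was 6.30 and wild high minus low soil pH was -2.51, a difference of 8.81 (adjusted p 0.00358). The difference between both line differences was tested in limma, and 158 probe sets passed, 51 with a higher and 107 with a lower lab difference. Of the 43 named genes past the threshold in the lab or wild comparison, 30 are among them. These genes were named for a large lab or wild difference on the same arrays, which favours a gap. Their number is thus not a separate result. For AT4G21650, at 0.14 in the lab and 6.30 in the wild comparison, the gap mostly restates the wild difference. Lab genes with a higher lab difference were AT5G16980 (2.85), AT5G15360 (3.11) and AT5G43450 (2.86). Those with a lower lab difference were AT3G07540 (-2.97), AT5G35480 (-2.73), AT3G19515 (-2.60), AT3G44630 (-4.05), THI2.2 (-4.38), AT4G15390 (-5.27), AT1G71020 (-4.60), AT1G06640 (-2.91), SKU5 (-3.21), AT5G12050 (-3.37) and AT5G63680 (-2.92).

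Wild genes with a negative lab minus wild value were AT4G21650 (-6.16), AT3G47250 (-5.87), AT4G36210 (-2.98), AT5G47250 (-2.45), AT4G12990 (-3.10) and AT5G37130 (-1.80). Those with a positive value were AT5G51620 (3.08), AT3G43740 (2.99), UGT78D1 (4.18), AT4G20480 (3.46), GLR2.7 (3.27), CYP71B24 (4.02), AT2G19310 (2.78), AT3G16700 (2.43) and AT3G57220 (1.99). A gap need not mean opposite directions. The lab and wild differences were both negative for AT5G51620 (-1.37 and -4.45), AT3G43740 (-1.39 and -4.38) and the lab gene AT3G07540 (-4.03 and -1.06), among others.

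AT3G47250, AT4G21650, AT5G51620 and UGT78D1 each have a signal near the bottom of the scale in 1 wild line. A sequence variant of that line under the probes may lower a probe set with no change in the transcript. If so, another probe set of the same gene would differ little. Of 59 genes with more than 1 tested probe set, 18 were called between some pair of lines, and their other probe sets had a median of 0.474 of the called change (95% bootstrap interval 0.234 to 0.621); 17 went the same way and 6 had under 0.25 of it. None of the 4 genes above is among the 18, and none of the 18 was called between the 2 wild lines. A variant and a transcript change thus cannot be told apart for these 4 genes. Nor can they for other named genes with a low signal, such as AT3G07540, AT5G35480 and AT3G19515 in the lab calcicole and AT3G43740 in the wild high soil pH line. AT4G29200 and scpl42 were low in 1 lab and 1 wild line, and a variant in both would also place them in both comparisons. None of these is among the 18 either. The same limit applies to the counts of line differences, and how many rest on variants was not tested. For the 18, the called probe set was the one with the smallest adjusted p. This choice lowers the ratio even where the transcript changed, so the value does not decide between the explanations.

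In 3 of 41 groups of 4 values 1 value lay far from the others, and chance gives about 1 in 20 groups. The CaCl2 change of AT5G62210 was 2.59 in the lab calcicole and 1.14 to 1.37 in the other lines. For AT2G44500 it was -1.50 in the wild low soil pH line and -1.07 to -1.02 in the others. The log2 ratio of the 3′ to the 5′ GAPDH control at 1 mM was 0.0802 in the lab calcifuge and -0.273 to -0.221 in the others.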

How the results depend on the processing

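Leaving out the plastid-encoded genes was added after the data were seen, and left the CaCl2 count at 2 and the lab against wild count at 0; the other alternatives were planned.

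Of 1093 values of 94 named results under the alternatives, 937 kept their direction and side of the threshold, 118 no longer passed, 38 newly passed and 0 reversed. The named CaCl2 and interaction genes had not passed, so keeping their side meant staying uncalled. The CaCl2 genes were named for moving the same way in all lines, so leaving out a line could not reverse them. The lab and wild genes were named for large differences, or for the same direction at both doses, so a reversal was unlikely for them too. With 1 array left out, 65 of 192 values of the wild genes and 24 of 208 of the lab genes no longer passed. The CaCl2 count of 2 was 1 with median centring, 30 with the pseudocount at the 25th percentile, 0 with no filter, 14 with the lower 60% left out, 32 with a variance trend, 103 at adjusted p under 0.1, 0 without shared probe sets, 0 without the line block and 26 by the 2-fold rule with no test. Leaving out 1 line gave 0 to 78.

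The lab count of 618 was 129 with no filter and 1438 at adjusted p under 0.1, and 123 to 509 with 1 array left out. The wild count of 45 was 12 with no filter, 21 with the lower 60% left out, 100 at adjusted p under 0.1, 108 with the wild arrays alone and 9 to 46 with 1 array left out. A line left with 1 array is assumed to vary like the others. The same-sign count of 8 was 13 with the higher pseudocount, 3 with no filter and 4 with the lower 60% left out. The count over pairs of lines fell from 2329 to 460 with no filter. The class response count was 0 to 5, and the lab against wild response count 0 to 1, with 1 line left out, which leaves 1 line on a side.

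The anthocyanin list's CaCl2 adjusted p was 0.260 with an estimated correlation and 0.0541 with fry. For the class response it was 0.000374 to 0.847 with 1 line left out, and its direction reversed without the lab calcifuge (0.164). The cause was not tested for any of these. Robust moderation was not run for the list test, which has no such option. Low signal limits genes near the pseudocount, whose changes depend on it.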

Other observations

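Chosen only after the results were seen were the added gene sets, and the tests of single plants at harvest, of degraded RNA, of green tissue, of the divisions of the lines, of the plastid-encoded genes without 4 members and of the divisions of the 8 arrays that part all 4 lines; the hypoxia set test and the brightness test were set before theirs.

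Of 24 salicylic acid-responsive loci listed, 6 were tested. The 4 of these whose values had not been seen had a mean CaCl2 change of -1.22, with 4 of 4 lower and 0 past the threshold over all probe sets, and line means of -1.31, -0.79, -1.79 and -1 (lab calcicole, lab calcifuge, wild high and wild low soil pH). The camera adjusted p over 15 tests was 1.56e-05, the estimated-correlation adjusted p was 0.256 and the fry adjusted p 0.0635. In the wild comparison their mean was -0.79 (camera adjusted p 0.0040, estimated-correlation adjusted p 0.318), and in the lab comparison 0.62 with 3 of 4 higher (0.269 and 0.751). The list has fewer than the 5 members required of the fixed lists. Iron-deficiency loci other than AT1G47400 had a mean CaCl2 change of 0.06 (7 members, camera adjusted p 0.969).

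Of 80 tests over 16 families, the UGT glycosyltransferases had a mean CaCl2 change of 0.33 (20 members, camera adjusted p 0.0148; -0.12 in the wild high soil pH line and 0.27 to 0.64 in the others) and a class difference of -0.52 (0.00188), and the CYP genes a lab line difference of 0.66 (11 members, 0.0371). The plastid-encoded genes passed in 3 comparisons: with CaCl2 (mean -0.37, 4.25e-05), by class (0.39, 0.0117) and, weighed further on, between lab and wild lines. The other 13 families passed in none. The estimated-correlation adjusted p was 0.990 for each of these calls. The UGT family kept members already named for the CaCl2 and class comparisons, so its tests there partly restate them. The actin 3′ control was at 1986 to 2517 on the lab arrays and 389 to 512 on the wild arrays. The hybridisation spike-ins, at 1 and 12.5 mM, had geometric means of 372 and 221 in the lab calcicole, 340 and 303 in the lab calcifuge, 266 and 269 in the wild high soil pH line, and 430 and 226 in the wild low soil pH line.

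Leading genes of the class difference in CaCl2 response, AT1G19530, AT4G10270 and AT3G10040, belong to the core response to low oxygen, and so further members were tested. Of 47 loci listed, 20 were tested. The 15 of these whose values had not been seen had a median class difference of 1.02 and a mean of 1.43 (-0.66 to 4.72). Of the 15, 11 were higher, 4 were lower and 0 passed the threshold over all probe sets. The camera adjusted p was 2.03e-07, the estimated-correlation adjusted p 0.365 and the fry adjusted p 0.369. A shift of the set would give such a median and camera p, but the other tests did not pass. The geometric mean signal of the 15 members at 1 mM was 73.1 in the lab calcicole, 216 in the lab calcifuge, 58 in the wild high and 107 in the wild low soil pH line, and at 12.5 mM 229, 183, 93.2 and 87.2. The arrays at 1 mM thus span 1.90 log2, so the oxygen supply of single plants at harvest and a response to CaCl2 by class cannot be told apart with 1 array per line and dose. Only 1 of 3 divisions of the lines, the real one, gave as large a mean (1.43, highest other 0.51), and 3 divisions are too few for a share under 0.05.

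Over 69 plastid-encoded genes, 0 of them past the threshold, the mean CaCl2 change was -0.62 in the lab calcicole and -1.31 in the lab calcifuge (63 lower and 6 higher in each), against 0.26 (5 lower, 64 higher) and 0.18 (26 lower, 43 higher) in the wild high and wild low soil pH lines. The lab minus wild mean was -1.19 (camera adjusted p 1.10e-39, estimated-correlation adjusted p 0.990, fry adjusted p 0.365). The set was chosen because psbB, atpH, atpI and rpoB led this comparison. Without these 4 the other 65 had a mean of -1.12, with 65 lower. The 65 genes were measured on the same arrays and are not independent replicates, so leaving out 4 is not an independent check. Brightness is argued against by nuclear probe sets of matched level (median -0.0128, 10000 draws -0.25 to 0.13, against -1.13). The 3′ to 5′ ratios of the GAPDH and ubiquitin controls shifted with dose by 0.113 on average in the lab lines (-0.09 to 0.27). That of actin, not part of this test, shifted by -0.02 and 0.15. These ratios argue against degraded RNA for nuclear transcripts, which the controls are. They cannot decide whether plastid transcripts were degraded. Less green tissue stays open: 4 nuclear photosynthesis genes had a median of -0.42 (-0.52 to -0.28), and 10 plastid-encoded genes within their range of signal a median of -0.91 (-1.13 to -0.38). Only 1 of 3 divisions of the lines, the real one, gave as large a mean (-1.19, highest other 0.39), too few for a share under 0.05, and the state of single plants was not tested.

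For the CaCl2 response, 1 of the 8 divisions of the arrays that part all 4 lines, the real one, gave as many as 2 probe sets (highest other 1), and 8 divisions are too few for a share under 0.05. By unadjusted p the real count was 1779 and the highest other 921. The 32 divisions that could be fitted with the line block hold 20 distinct fits, with 1356 as the highest other count by unadjusted p, and cannot give a share under 0.05 either. For the class and the lab against wild differences in response, 3 of 3 divisions gave as many as the real 0 (highest other 0), which any division would, so this tests nothing.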
